A study of Cannabis sativa with 6 samples.

How the data were processed

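RNA was measured by sequencing in 6 flower libraries of feral hemp (Cannabis sativa), a dioecious plant with separate female and male individuals. Per the labels, 3 libraries came from female and 3 from male flowers, and each sex was represented once from each of 3 Nebraska locations, written Knox, Madison and Merick. Per the labels' protocols, plants were grown in pots under growth chamber and greenhouse conditions, flowering was induced by a shorter day, RNA was purified on columns with DNase treatment, and libraries followed standard Illumina procedures. A library is named here by its location and sex. The libraries of one sex carry different locations in the labels. Whether a library is 1 plant or a pool is not given in the sources used here, so p-values measure the spread between these libraries. Flower stage and sequencing batch are also not given there.

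The authors deposited raw counts per gene, 1 table per library, each with 29777 gene rows and 5 closing rows for reads assigned to no gene. Those closing rows carry the row names that the htseq-count program writes, but the aligner, the counter, the genome build, the annotation and the strand setting are not given in the sources used here. The closing rows were left out of library sizes and tests. They held between 14.9% of listed reads (Madison female) and 18.1% (Knox male), of which reads without a unique alignment made up 5.14% to 5.74% of listed reads. Because such reads were not assigned to genes, genes with near-identical copies are undercounted or uncertain. Without a known strand setting, overlapping and antisense genes are uncertain too. Gene counts summed to between 26945432 (Knox female) and 46045338 (Merick male) per library. Counts are reads without molecular identifiers, so counting intervals and floors cover counting error only.

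Gene identifiers were NCBI LOC symbols (29283 rows), transfer RNA symbols (476 rows) and mitochondrial locus tags (18 rows). Names were looked up in an NCBI RefSeq gene table of the Cannabis sativa Pink pepper assembly. It held 23050 of the LOC symbols and all 18 mitochondrial tags. The table gives no gene descriptions, and it pairs only 6 LOC symbols of these count tables with a common name. The 23 gene lists fixed before the data were examined relied on descriptions, so none could be used and their tests were not run. Because the build behind the counts is not known, no positions are printed. The table was used for names, for the chromosome on which a gene lies in the Pink pepper assembly, and for which genes neighbour each other there.

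The comparison of male with female flowers used edgeR 4.0.16 in R 4.3.3: trimmed mean of M-values (TMM) scaling, the filterByExpr filter (19276 genes kept), robust dispersion estimates, the quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. All 6 libraries entered the fit without covariates, which leaves 4 residual degrees of freedom. Log2 fold changes are male minus female, and their standard errors (SE) are the fold change divided by the square root of the test's F statistic. Levels are CPM, the field's depth-scaled count, on TMM-scaled library sizes, with the SD over the 3 libraries of a sex. Where a sex had 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the whole sex. Where it had 1 to 3 counts, the pooled ratio is given with an exact Poisson 95% interval. Chromosomes with at least 20 tested genes were compared by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Locations were compared by an F-test of the location term in a model with sex, which leaves 2 residual degrees of freedom.

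The rule for named genes, fixed before the data were examined, took the 6 genes with the largest fold change in each direction among genes past the threshold with an average log2 CPM of at least 3 and no overlap between the sexes. Its requirement of an informative description could not be applied and was dropped. The 6 genes with a common name, the 3 mitochondrial ribosomal RNA genes, the genes found in one sex only and the order of genes along X were chosen after the data had been examined.

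On simulated counts drawn from the 19276 genes' means, dispersions and library sizes, the male against female test called 9 of 50 genes changed 4-fold, 38 of 50 changed 16-fold, 42 of 50 changed 64-fold and 48 of 50 changed 256-fold. Every called gene had the right direction, and 6 unchanged genes were called. A simulated shift of -1 (log2) of all X genes was called by the chromosome test, and no other chromosome was. The simulated genes were drawn independently, and the shift was larger than the observed X median of -0.20. It therefore does not show that a shift of the observed size would be called. The alternatives were other scalings (relative log expression, upper quartile, library size only), other filters, DESeq2 1.42.0, limma-voom, a test against a fold of 2, a threshold of 0.01, thinning to equal depth, location as a block, and leaving out each library in turn.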

Results

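Gene expression was measured in 3 female and 3 male flower libraries of feral hemp, 1 of each sex from Knox, Madison and Merick. Gene counts ranged from 26945432 to 38672535 in the female libraries and from 40334171 to 46045338 in the male libraries. Between 20260 and 20625 genes had at least 1 count in a female library, and between 21784 and 22015 in a male library. The design addressed how messenger RNA levels differ between female and male flower tissue.

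Sex was the main axis of variation. The first principal component of log2 CPM carried 68.1% of the variance and placed the female libraries between -155 and -135. The Knox and Madison males lay at 191 and 192, and the Merick male lay at 47.6. Correlations of log2 CPM were 0.90 to 0.93 among females and 0.93 between the Knox and Madison males. The Merick male correlated at 0.79 and 0.82 with the other males and at 0.76 to 0.78 with the females.

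**Figure D1:**
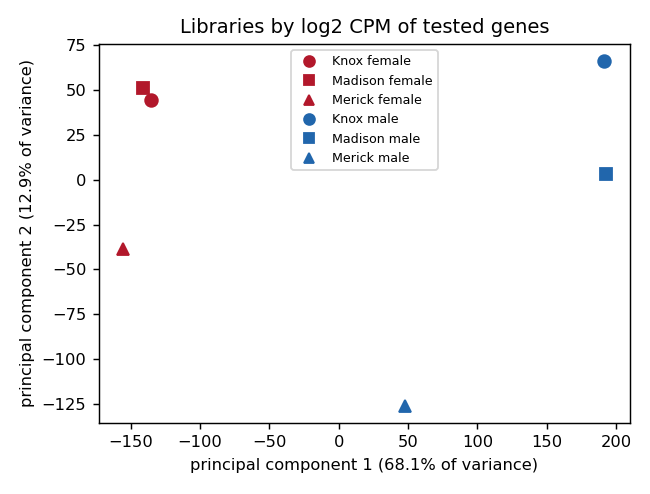
First against second principal component of log2 CPM over the tested genes; colours mark sex and symbols mark location, 1 point per library. The females sit between -155 and -135 on the first component, the Knox and Madison males near 191 and 192, and the Merick male between them at 47.6.

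Of 19276 tested genes, 2424 were higher in male and 915 were higher in female flowers by edgeR's quasi-likelihood test (adjusted p under 0.05). Of these called genes, 938 were at least 16-fold higher in male and 77 at least 16-fold higher in female flowers by fitted fold change. These counts were 1243 and 437 without the Merick male, 554 and 32 without the Knox male, 161 and 10 without the Madison male, and 109 to 163 and 6 to 22 without any one female. Over all tested genes, called or not, 1050 and 123 had such a fold change, and 999 to 1415 and 133 to 602 with 1 library left out. Without regard to size the directions were closer: every male lay above every female for 4671 genes (24.2%) and below for 3815 (19.8%), where chance gives 5% each. In all, 200 genes reached 1 CPM in every male library with at most 3 counts over all female libraries. The reverse held for 4 genes. With 0 counts required in the other sex, 107 and 2 genes met the criterion. Another assignment of the 6 libraries to groups of 3 gave at most 5 such genes in either direction. Each such assignment puts both sexes in both groups, so genes limited to one sex could not meet the criterion there. That maximum therefore does not test the 200 male-only genes, and it was above the 4 female-only genes.

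The 6 genes with the largest male excess were LOC115700758, LOC115717719, LOC115717456, LOC115695321, LOC115724967 and LOC115695248. None had a count in any female library, and their male means lay between 159 and 204 CPM. Against a floor of 3 counts over the females, they were at least 5414-fold to at least 6928-fold higher in male flowers. The table of gene names lists 5 of them as protein coding, does not hold LOC115695321, and places LOC115717719 on X in the Pink pepper assembly. Their levels differed among males. LOC115717719 stood at 426 CPM in the Merick male, 151 in the Madison male and 3.64 in the Knox male. LOC115700758 stood at 319, 278 and 14.7 CPM in the same order. LOC115695321 was lowest in the Merick male, at 38.9 CPM against 273 in the Madison and 174 in the Knox male. LOC115695248 varied least, at 159 ± 61.6 CPM (SD, n = 3), with an adjusted p of 0.0071 in edgeR's test. It and LOC115717456 passed the threshold under each scaling and filter run, with DESeq2 and limma-voom, and without any one library. The other 4 missed it without any one female or without the Madison male (edgeR's adjusted p 0.052 to 0.11), and LOC115700758, LOC115717719 and LOC115724967 also with limma-voom (adjusted p 0.070 to 0.22).

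The 6 genes with the largest female excess were LOC115708921, LOC115712431, LOC115718819, LOC115700526, LOC115717255 and LOC115704295, all listed as protein coding. LOC115708921 averaged 72.4 ± 62.4 CPM in females (SD, n = 3) and had 3 counts over all males, a pooled ratio of 2846 (95% Poisson interval 974 to 13803). Its level ran from 8.66 CPM in the Merick female to 133 in the Knox female. Its log2 fold change of -11.4 moved to -10.6 without the Knox female and to -12.3 without the Madison male. LOC115712431 averaged 21.4 ± 13.02 CPM in females and had 2 counts in males, a ratio of 1274 (353 to 10519). LOC115700526 was the most abundant, at 176 ± 156 CPM in females and 0.24 ± 0.14 in males. LOC115704295, on X in the Pink pepper assembly, averaged 95.5 ± 49.7 CPM in females and 0.17 ± 0.15 in males (log2 fold change -9.11, SE 1.07, adjusted p = 0.011 by edgeR). For LOC115700526 the female libraries ranged from 12.8 CPM in Merick to 323 in Knox. LOC115712431 passed the threshold under each scaling and filter run, with DESeq2 and limma-voom, and without any one library. The other 5 missed it without the Knox female, the Madison female or the Madison male (edgeR's adjusted p 0.052 to 0.074), and LOC115700526 also without the Knox male (0.053). LOC115708921 and LOC115700526 missed it with limma-voom (adjusted p 0.092 and 0.13).

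The 4 genes found in females only were LOC115708921, LOC115712431, LOC115720519 and LOC115697026, the last pair named after their values were seen. LOC115697026 is listed as a long non-coding RNA on X in the Pink pepper assembly. It stood at 1.63 ± 0.22 CPM in females (SD, n = 3), with 167 counts there and 0 in males, at least 68.2-fold higher (adjusted p = 0.018 by edgeR). LOC115720519 stood at 3.29 ± 3.03 CPM in females with 0 counts in males, at least 138-fold higher (adjusted p = 0.025 by edgeR). Its level was 6.78 CPM in the Knox female, 1.56 in the Madison and 1.52 in the Merick female. Without the Knox female its log2 fold change moved from -9.96 to -8.94. Both genes missed the threshold without any one female or without the Madison male, and LOC115720519 also without the Knox male. In these fits edgeR's adjusted p was 0.057 to 0.088. Without the Merick male, 24 genes met the female-only criterion. Without the Knox, Madison or Merick female, 8, 10 and 14 genes met it, and without the Madison male 15 did. Leaving out a library loosens the criterion, so the count could only stay or rise.

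Among the 6 genes with a common name, 1 was called between the sexes. OAC (LOC115723438) encodes olivetolic acid cyclase, which acts in the synthesis of olivetolic acid, a cannabinoid precursor, and it was lower in male flowers. It averaged 263 ± 198 CPM in females and 9.24 ± 10.8 in males (SD, n = 3; log2 fold change -4.83, SE 1.28, adjusted p = 0.048 by edgeR). Every female was above every male, but the call was lost without any one library other than the Merick male (adjusted p 0.084 to 0.16 by edgeR). It was also lost with upper-quartile scaling, library size only, no filter or limma-voom (adjusted p 0.052 to 0.059), while DESeq2 kept it. CBDAS (LOC115697762), the enzyme that forms cannabidiolic acid, averaged 189 ± 103 CPM in females and 24.3 ± 39.1 in males (log2 fold change -2.96, SE 1.62, adjusted p = 0.23 by edgeR). The polyketide synthase locus listed as PKSG2, PKSG4 and PKSF3 (LOC115699293) averaged 64.7 ± 27.5 and 20.6 ± 26.1 CPM (adjusted p = 0.29). CHS (LOC115724170), chalcone synthase of the flavonoid pathway, averaged 1024 ± 811 and 331 ± 230 CPM (adjusted p = 0.16). TPS1 (LOC115716064), a terpene synthase, averaged 33.7 ± 27.8 and 17.8 ± 25.4 CPM (adjusted p = 0.68). The locus listed as CBDAS2, CBDAS3 and THCA5 (LOC115696884) had 16 counts in the Merick female and 10 in the Merick male. It had 0 in the other libraries and was below the filter. Adjusted over the list alone, OAC was again the 1 call among the 5 tested genes (adjusted p = 0.040 by edgeR); this list was formed after the data had been examined.

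The Merick male had the highest level of the 3 males in each of the 5 tested genes. CBDAS was at 69.5 CPM in the Merick male, against 2.94 in the Madison male and 0.52 in the Knox male. The PKSG locus was at 50.5, 9.12 and 2.19 CPM, and TPS1 at 46.9, 5.64 and 0.75 CPM, in the same order. CHS was at 591, 249 and 154 CPM. OAC was at 21.6, 4.53 and 1.60 CPM in that order, all below the 47.0 CPM of the lowest female. Without the Merick male, edgeR called CBDAS (log2 fold change -6.78, SE 1.10, adjusted p = 0.0068), OAC (-6.43, adjusted p = 0.012), the PKSG locus (-3.52, adjusted p = 0.016) and CHS (-2.35, adjusted p = 0.047) lower in male flowers. TPS1 (-3.40, adjusted p = 0.11) was not called there. That fit called 8311 genes in all. Leaving out the highest male lowers the male mean, so the larger differences follow in part from that choice. Without any one other library, none of the 5 genes was called (adjusted p 0.084 to 0.93 by edgeR). CBDAS belongs to a family of near-identical copies, and its counts are uncertain to that extent.

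**Figure D2:**
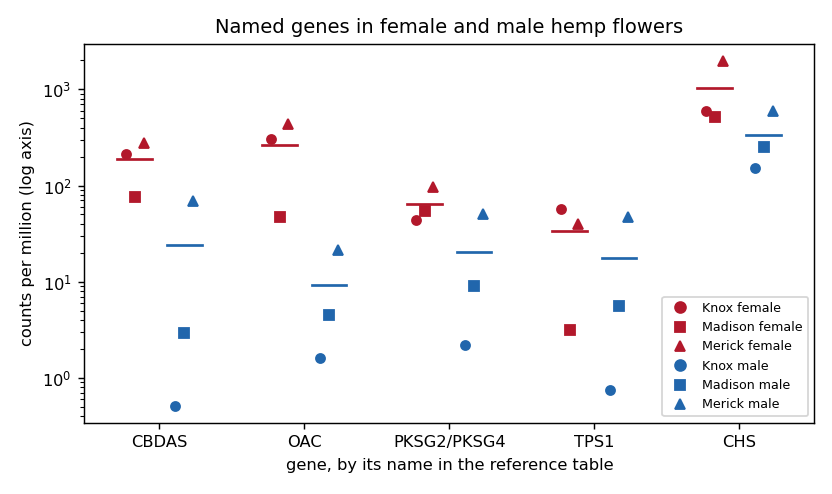
CPM (log axis) of 5 genes with a common name in each library; red marks female and blue male libraries, symbols mark location, and bars mark the mean of 3 libraries. CBDAS lies between 75.7 and 278 CPM in females and at 0.52, 2.94 and 69.5 CPM in the Knox, Madison and Merick males.

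None of the 3 mitochondrial ribosomal RNA genes was called between the sexes by edgeR. The small-subunit gene rrnS averaged 168 ± 31.0 CPM in females and 78.98 ± 31.3 in males (SD, n = 3; adjusted p = 0.079 by edgeR). The large-subunit gene rrnL averaged 165 ± 38.0 and 102 ± 19.6 CPM (adjusted p = 0.14 by edgeR). Without the Merick male, rrnS passed the threshold (adjusted p = 0.012 by edgeR). DESeq2 called rrnS (adjusted p = 0.025) and the 5S gene rrn5 (adjusted p = 0.037; 0.14 by edgeR).

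The number of genes called between the sexes moved with single libraries. edgeR called 8311 genes without the Merick male, of which 4592 were higher in male and 3719 higher in female, and 3327 of the 3339 calls over 6 libraries were among them. It called 943 genes without the Knox male, 216 without the Madison male, and 131, 132 and 242 without the Knox, Madison and Merick female. The share of calls that were higher in male was 72.6% over 6 libraries, 55.3% without the Merick male and between 76.9% and 91.2% without another library. DESeq2 called 6437 genes over 6 libraries, 60.9% of them higher in male.

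A second question was whether X-linked genes as a set differ between the sexes. X genes were called higher in female more often than autosomal genes: 151 of 2120 tested X genes (7.12%) against 718 of 15237 autosomal genes (4.71%; Fisher's exact test, two-sided, p = 5.7e-06). They were called higher in male less often, with 204 X genes (9.62%) against 2051 autosomal genes (13.5%; Fisher's exact p = 3.9e-07). The Benjamini-Hochberg values over both tests were 5.7e-06 and 7.7e-07. Genes are not independent replicates, so these p-values are too small. The median log2 fold change was -0.20 on X and 0.02 on the autosomes. In the planned camera test, which allows for correlated genes through the preset correlation of 0.01, no chromosome passed the threshold. X had the smallest p, 0.080 (adjusted p = 0.80 by limma's camera), and an adjusted p = 0.37 with an estimated correlation. The excess of female-high X genes was no longer past 0.05 without any one female or without the Madison male (Fisher's exact p 0.056 to 0.69). The X share there was 0.092% against an autosomal 0.077% without the Knox female, up to 0.51% against 0.26% without the Merick female. These fits called only 15 to 56 genes higher in female over all tested genes. Such shares rest on few X genes and do not show that the excess persisted. The deficit of male-high X genes was no longer past it without the Merick female or the Madison male (Fisher's exact p 0.64 and 0.22). In each of these fits far fewer genes were called than over 6 libraries.

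The median was not even along X. This was examined after the data had been seen, and the stretch below was chosen for its low median, so no test of it is given. Tested X genes were taken in their order along X in the Pink pepper assembly. The last 900 had a median log2 fold change of -0.39, against -0.07 for the other 1220 X genes and 0.02 for the autosomes. Of its called genes, 91 were higher in female and 57 were higher in male. Relative to the autosomes of the same library, the median of these 900 genes was -0.48 in the Knox male, -0.53 in the Madison male and -0.29 in the Merick male. It was 0.04, 0.04 and -0.05 in the Knox, Madison and Merick females, each against the other females, which holds the female values near 0. The last 8 full groups of 100 genes had medians of -0.59 to -0.29. Of 148 such autosomal groups, 6 lay at or below -0.29. No autosomal run of 900 neighbouring genes had a median below -0.11, while the lowest on X was -0.39.

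**Figure D3:**
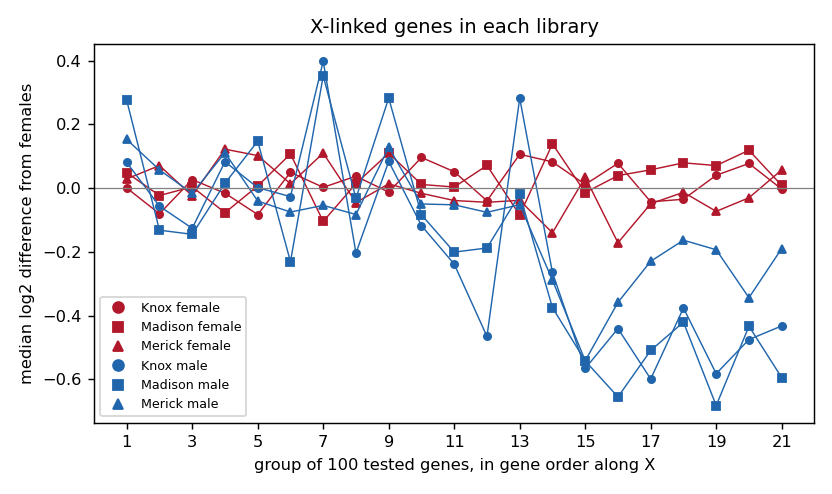
Median log2 difference from the females (other females, for a female library) over groups of 100 tested genes in gene order along X of the Pink pepper assembly, 1 line per library; red marks female and blue male libraries. Over the last 8 groups all 3 males lie below 0, while the females, measured against each other, stay near 0.

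A further comparison asked whether flowers from the 3 locations differ, with sex as a covariate. No gene passed the threshold in edgeR's test, and the smallest adjusted p was 0.71. At an unadjusted p under 0.05 there were 1336 genes, 6.93% of those tested, where 5% would be expected by chance. DESeq2's likelihood-ratio test called 689 genes on the same counts. With 1 female and 1 male per location, 2 residual degrees of freedom remained, so edgeR's count of 0 does not show that locations are alike.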

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

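The results below were singled out after the data had been examined, and no explanation of them was tested.

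Reads that overlapped more than 1 gene and were therefore left unassigned made up 0.20% ± 0.01 of listed reads in females and 0.44% ± 0.08 in males (SD, n = 3), a difference of 0.242 percentage points in data that enter no comparison of genes. Every male (0.35% to 0.48%) lay above every female (0.19% to 0.21%), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

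For TPS1 (LOC115716064), the male and female libraries of one location differed with a sign that varied between locations. On the log2(CPM + 0.1) scale male minus female was -6.09 in Knox, 0.83 in Madison and 0.22 in Merick. The Madison female was low, at 3.13 CPM against 57.6 in the Knox and 40.3 in the Merick female. The locations were not taken to pair the libraries. There is 1 library per sex and location, so a difference between locations cannot be told from the spread between libraries and was not tested.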

How the results depend on the processing

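The choice of library and of test decided how many genes were called between the sexes. The count of 3339 lay between 131 and 8311 when 1 library was left out. It was 6437 with DESeq2, 998 against a fold of 2, 142 at an adjusted p under 0.01, and 2123 with location as a replicate block. The cause was not tested. The locations were not taken to pair the libraries: deviations of the female and male of one location from their sex means correlated at 0.12 (Knox), -0.00078 (Madison) and 0.17 (Merick), and the Madison female correlated better with the Knox male (0.14). The other scalings, filters, limma-voom and equal depth gave 2347 to 3363 genes. DESeq2 called 60.9% of its genes higher in male, against 72.6%. Upper-quartile scaling moved the median log2 fold change of all genes to -0.18 and keeping all genes with a count moved it to 0.18. Over all named genes and alternatives, 265 values kept their direction and side of the threshold. Another 58 kept only their direction, 7 moved past the threshold and none reversed. The genes of the named-gene rule were chosen for no overlap between the sexes. Their direction could therefore not reverse when a library was left out. OAC missed the threshold (adjusted p 0.052 to 0.059) under upper-quartile scaling, library size only, no filter, the block and limma-voom. With the block CHS passed it (adjusted p = 0.049), and LOC115697026 and LOC115720519 missed it (0.073 and 0.060). No chromosome was called under any alternative run. For locations, DESeq2 called 689 genes and each edgeR alternative 0. Requiring 0 counts in the other sex left 107 male-only and 2 female-only genes. Genes called at least 16-fold higher in male numbered 511 (limma-voom) to 1038 (DESeq2), and in female 53 (block) to 116 (DESeq2), with all libraries. Leaving out 1 library gave 5 to 24 female-only genes, a count that could only stay or rise. The share of X genes called higher in female exceeded the autosomal share by 2.41 percentage points, and by 0.015 to 4.83 with 1 library left out. For genes higher in male the difference was -3.84, and -4.34 to -0.13 with 1 library left out. Both differences were small where few genes were called, so their size alone does not show that the X pattern faded. The last 900 X genes differed from the autosomes by -0.48 to -0.37 (log2) with 1 library left out. The difference was -0.41 under upper-quartile scaling, -0.42 with the block, -0.47 among genes of at least 2 log2 CPM and -0.44 for a shorter stretch at the end of X. A scaling factor per library cancels in this difference, and the stretch was chosen for its low median. These values therefore do not test the pattern. The planned tests of gene lists were not run, since no descriptions were at hand. Thinning to the smallest library gave 3363 genes, so unequal depth among these libraries did not set this count. It does not show what greater depth would give. The X, one-sex, 16-fold and share alternatives were chosen after seeing the data; the others were chosen before the data were examined.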

Other observations

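All tests below were chosen after the pattern had been seen, except the other assignments of the libraries to groups and the removal of called genes from X.

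Called genes tended to lie beside each other. In the gene order of the Pink pepper assembly, 413 adjacent pairs of tested genes were called in the same direction, 1.21 times the mean of 340.6 over 1000 shuffles within chromosomes. The highest shuffle gave 390, and 0 of the 1000 shuffles reached the observed count. This fits the hypothesis that neighbouring genes change together between the sexes, but that hypothesis restates the adjacency and names no cause. Tandem copies that share reads may add to the count, which was not tested.

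The real assignment called 3339 genes and each of the other 9 assignments of the 6 libraries to groups of 3 called 0, so 1 of 10 was as large. For chromosomes, all 10 of 10 gave 0. These assignments are too few for a share under 0.05.

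The Merick male lay between the sexes. Measured on genes chosen without it, it had gone 57.9% of the way from the female to the male level for 2553 male-high genes and 25.9% for 2508 female-high genes. A female library labelled male is argued against: 73 genes had 0 counts in every female and at least 5 CPM in the Knox and Madison males, and 58 of them (79.5%) reached 1 CPM in the Merick male. A mixture with female tissue like that sampled is argued against as the whole cause, since one share would have to serve all of 22 female genes nearly absent from the other males; 7 allow a share under 10% and 12, CBDAS among them, need over 10%. The location stays open: the Merick female and male deviated together only weakly (correlation 0.17) and there is 1 male per location, and flower stage may differ and was not tested.

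Genes in one part of X were lower in males, by -0.41 (log2) against autosomes of the same libraries; a scaling factor per library cancels in this difference, so it does not test scaling. Of the 900 genes 62.2% were lower in male, against 46.2% to 52.8% in 13 autosomal runs of 900 genes. The stretch was chosen for its low median, so this share restates the pattern. This share cannot decide whether under 5% of the genes carried the difference, since choosing a low median already favours a high share. The test planned for a few strongly female-high genes decides nothing: without called genes the difference was -0.22, but the calls themselves set which genes were removed, and the autosomal median moved from 0.02 to -0.11. Within the stretch every male was low, and the highest male value was -0.29, in the Merick male. The stretch was chosen for its low median over these same males, and all were measured against the same females. These values therefore do not test the pattern itself. A single aberrant male would leave the other males level with the autosomes. The difference was -0.48, -0.38 and -0.37 without the Merick, Knox and Madison male in turn. For this stretch, that argues against a single aberrant male. A pair of further readings cannot be told apart by these counts, because both predict a lower X end in males. One is X genes without a Y partner, present once in males. The other is Y copies whose reads differ too much from an X reference to be counted. The size of the median, -0.39, was not set against either.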
